A study of Mus musculus with 5 samples.

How the data were processed

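5hmC was profiled by hMeDIP-seq in 5 mouse libraries. Per the labels' protocols, sonicated genomic DNA was ligated to adaptors, immunoprecipitated, amplified by PCR and size-selected. ES and iPS cells were grown on a layer of mouse feeder cells, per the labels, so that DNA of feeder cells can be part of those libraries. Each deposited file lists 40 bp read positions, 1 row per read, and its other number columns were all 0 when checked, so the deposited files hold no count column, score or signal. The build is mm9, per the submitters' processing notes. The largest read end on chromosome 1, 197195379, lies beyond the last gene of the GRCm38 gene table at 195291439. Reads can lie past a last gene, so this alone does not settle the build. The aligner and its filters are not given in the sources used here. Reads that map to repeats depend on those filters.

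Reads were collapsed to 1 per chromosome, strand and 5' position in each library, since reads without molecular identifiers can be PCR copies. Each was placed at the midpoint of a fragment extended to 200 bp, 100 bp from its 5' end. Chromosomes 1 to 19 and X were used, with 19590343 collapsed reads in R1, 20338362 in the fibroblast library titled OSKM, 21140420 in the one titled TSKM, 20014810 in OT-iPS and 20731425 in TSKM-iPS. Reads were counted in 10 kb bins, kept where the mean was 10 or more per library, and scaled by the trimmed mean of M values (30% of M and 5% of A values trimmed), with factors of 0.967, 1.02, 1.03, 0.981 and 0.999 in the same order. A bin at the median of the quintile with the highest signal has 7.20 CPM, and counting error limits what can be seen in the lowest quintile, at 1.43 CPM.

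An annotation of mm9 was not used here. Gene body, promoter, gene list and reprogramming factor tests planned before the data were examined were therefore not run, and 10 kb bins, set as the main result for this case, were tested instead. Regions are given by position alone, with no gene, exon or intron. The planned count model was replaced by limma (3.58.1, R 4.3.3), its trend test on log2(CPM + 1), as the plan foresaw for files with read positions. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The pluripotent class holds R1, OT-iPS and TSKM-iPS, and the fibroblast class both fibroblast libraries. The contrast of iPS with ES was fitted in the same way over 3 groups. The rule for named bins, set before the data were examined, took the 5 highest and 5 lowest log2 fold changes among called bins. For 1 library against 1 it took the 8 highest and 8 lowest log2 ratios with a mean of 50 or more reads, a rule written for genes and applied to bins, and the text gives those at the ends and those that lie together. These ratios have 95% exact intervals for a ratio of 2 Poisson counts, which cover counting error only. Neither the iPS nor the fibroblast pair looked like 1 library deposited in duplicate, since each pair differed by more than counting error.

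The test was run on simulated counts with 200 changed bins per fold among about as many bins as in the data. All simulated changes were rises in the fibroblast or in the iPS libraries, and falls were not simulated. For fibroblast against pluripotent it found 45.5% of 1.5-fold, 93.5% of 2-fold and 100% of 4-fold changes (245801 bins, 22 unchanged bins called). For iPS against ES it found 12% of 1.5-fold, 66% of 2-fold and 99.5% of 4-fold changes (245830 bins, 23 unchanged bins called). All simulated libraries came from 1 mean profile, with a dispersion of 0.0034 taken from the iPS and fibroblast pairs. R1 was thus given no spread beyond that of these pairs. The shares found can therefore be higher, and the unchanged calls fewer, than in the data.

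Enriched windows were 1 kb windows with more reads than a Poisson p of 1e-05 allows at the library's mean, after each library was thinned to 19590343 reads. Of 200 simulated windows raised 4-fold, 92.5% were found, with 10 unchanged windows called among 2429797 simulated in all. The unchanged windows had a flat mean and Poisson counts, so that the limit itself sets how many were called. The simulation does not give the share of false calls in the libraries, whose window counts had an SD of 1.07 to 1.30 times the mean. Windows up to 5 kb apart were joined into regions. Without an input library, copy number and mappability act on these calls. Chromosome ratios are medians over bins of 1 library over the median of the other 4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives changed scaling, test, filter, pseudocount (0.25 and 4), collapsing, bin and window size, chromosomes and libraries.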

Results

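5-Hydroxymethylcytosine (5hmC), the oxidised form of methylcytosine made by the Tet enzymes, was mapped by hMeDIP-seq in 5 mouse libraries. In this assay an antibody enriches sonicated DNA fragments that carry the mark, and the fragments are then sequenced. The R1 library came from an embryonic stem (ES) cell line and was the only library of its group. Both induced pluripotent stem (iPS) libraries came from cells reprogrammed with factor sets that include Tet1. OT-iPS was made with Oct4 and Tet1, and TSKM-iPS with Tet1, Sox2, Klf4 and c-Myc. The remaining 2 libraries came from fibroblasts of iPS-derived mice given doxycycline, which switches the integrated factors on again (secondary induction). For these the labels disagree. The library titled OSKM has a source name with TSKM, and the library titled TSKM has one with OSKM. The titles give 3 days of doxycycline for both, while the sample characteristics give 3 for the first and 4 for the second. They are therefore called the fibroblast libraries titled OSKM and titled TSKM, and no direction is drawn for a factor.

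The files held 20836505 reads for R1, 21546447 for the fibroblast library titled OSKM, 22669162 for the one titled TSKM, 21287967 for OT-iPS and 21976789 for TSKM-iPS. Between 5.45% and 6.51% of reads repeated an earlier position in their library. Libraries of 1 group came from different lines, so the spread between them is a spread between lines, and nothing in the labels names separate cultures of 1 line. No input, IgG or spike-in library was used here, so values are relative within a library and give no absolute amount of 5hmC.

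The first comparison asked how the profile of the doxycycline-treated fibroblasts differed from that of pluripotent cells. Most 10 kb bins that differed were lower in the fibroblast libraries, and these lay mainly where the 5hmC signal was high. On chromosome 5, bin 66410001 to 66420000 (mm9) had 2.62 ± 0.579 CPM (reads scaled to library depth by TMM; SD, n = 2) in the fibroblast libraries and 10.1 ± 0.718 (SD, n = 3) in the pluripotent libraries, a 3.85-fold lower level. On chromosome 7, bin 140300001 to 140310000 went the other way, with 7.30 ± 1.09 CPM in the fibroblast libraries and 3.14 ± 0.150 in the pluripotent libraries, 2.33-fold higher.

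The other bins with the largest falls were on chromosomes 5 and 8. Bin 116060001 to 116070000 of chromosome 5 had 5.16 ± 1.26 CPM in the fibroblast libraries against 16.1 ± 2.14 in the pluripotent ones. On chromosome 8, bin 91550001 to 91560000 had 4.22 ± 0.195 against 14.7 ± 6.02 CPM. Bin 123090001 to 123100000 had 7.64 ± 0.615 against 23.1 ± 8.30 CPM, and bin 90300001 to 90310000 had 4.64 ± 0.646 against 14.0 ± 4.42 CPM. The wide spread of these chromosome 8 bins came with a high R1 value. For bin 91550001 R1 had 21.6 CPM, OT-iPS 12.0 and TSKM-iPS 10.5. The bins with the largest rises besides that of chromosome 7 were on chromosomes 1, 3 and 17. On chromosome 3, bin 117740001 to 117750000 had 4.98 ± 0.361 CPM in the fibroblast libraries against 2.07 ± 0.221, and bin 126320001 to 126330000 had 8.11 ± 1.69 against 3.68 ± 0.213. Bin 140380001 to 140390000 of chromosome 1 had 5.70 ± 0.152 against 2.47 ± 0.456, and bin 73270001 to 73280000 of chromosome 17 had 8.88 ± 2.37 against 4.12 ± 0.878. In all 10 named bins the fibroblast and pluripotent libraries did not overlap, which the choice of the most extreme called bins favours.

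**Figure D1:**
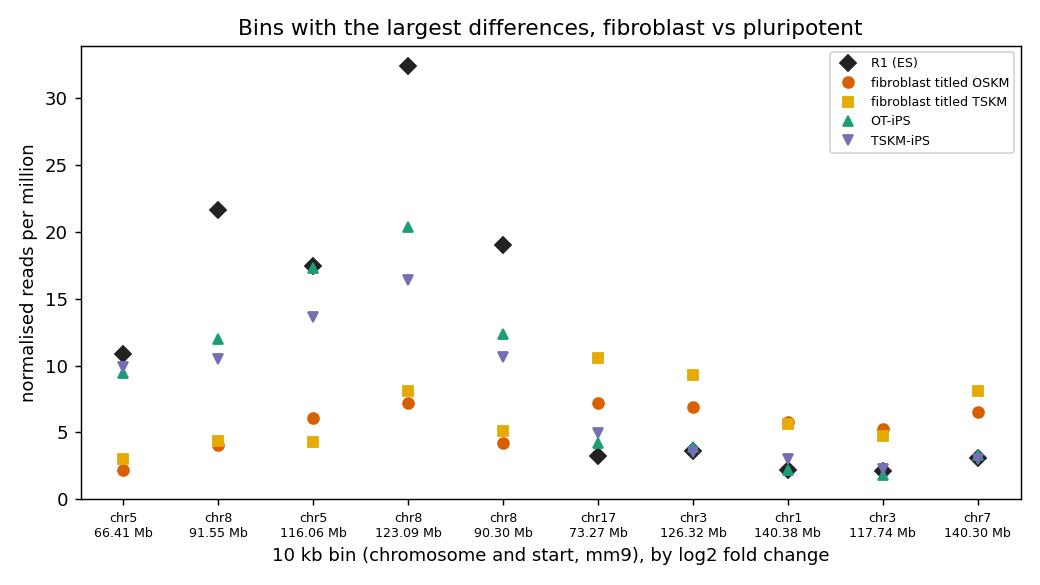
CPM (y axis) in the 5 bins with the largest falls and the 5 with the largest rises in the fibroblast libraries (x axis, chromosome and start in mm9, ordered by log2 fold change). Each point is 1 library; in the chromosome 5 bin at the left both fibroblast libraries lie at 2.21 and 3.03 CPM, below the pluripotent libraries at 9.48 to 10.9 CPM.

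Across the genome, 6461 of 245981 tested bins passed an adjusted p of 0.05 in limma's trend test on log2(CPM + 1), of which 5467 were lower and 994 higher in the fibroblast libraries. Lower bins were thus 84.6% of the calls, and 69.7% of 4793 calls when libraries were scaled by their size alone. When R1 was left out they were 61.3% of 32416 calls, with 12550 bins higher. With the strain label as a covariate 15835 bins passed, and with each library's trend on signal removed 1736. The log2 fold change was -1.62 ± 0.15 (SE, limma adjusted p = 0.000159) for bin 66410001 of chromosome 5 and 1.00 ± 0.15 (limma adjusted p = 0.00362) for bin 140300001 of chromosome 7, on a scale that understates changes of low bins. The groups did not overlap in 37.2% of tested bins, and part of that arises by chance with so few libraries. A fit with 1 fibroblast library takes its spread from the pluripotent libraries alone, and the lone library is assumed to vary like them. Without the one titled OSKM 0 bins passed in limma (25948 at an unadjusted p under 0.05), and without the one titled TSKM 1 bin passed (22225 at an unadjusted p under 0.05). The log2 fold change of bin 66410001 of chromosome 5 was then -1.46 and -1.78, and that of bin 140300001 of chromosome 7 1.13 and 0.86. Without OT-iPS 1839 bins passed and without TSKM-iPS 4072. Without R1, or with R1 as a group of its own, 32416 and 37033 bins passed.

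Called bins followed the level of signal. In the quintile of tested bins with the highest mean signal, 3028 bins were lower and 31 higher in the fibroblast libraries, and in the next quintile 1771 were lower and 159 higher. In the second lowest quintile the order turned, with 350 higher and 106 lower. The lower bins formed 4414 stretches, of which 205 held 3 or more bins, and the higher bins formed 954, of which 3 did. The longest were 80 kb on chromosome 8, from 34930001 to 35010000 and from 122080001 to 122160000. Next came 70 kb on chromosome 5, from 75980001 to 76050000, and 70 kb on chromosome 17, from 66660001 to 66730000. In the first of these R1 had 11.1 CPM, OT-iPS 7.02 and TSKM-iPS 7.10, against 4.16 and 4.54 in the fibroblast libraries, so R1 stood apart there. In the chromosome 17 stretch the mean was 4.47 and 4.27 CPM in the fibroblast libraries and 9.93, 8.09 and 8.17 CPM in R1, OT-iPS and TSKM-iPS. Among rises, called stretches at 126310001 to 126340000, 126350001 to 126380000 and 126390001 to 126410000 lay side by side on chromosome 3. Their fibroblast means were 6.92 to 8.75 CPM and their pluripotent means 3.44 to 4.76 CPM. On chromosome X 0.346% of bins were called. Chromosome 8 had 4.55%, but there the R1 library was raised along the whole chromosome, with a median ratio to the other libraries of 1.23.

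**Figure D2:**
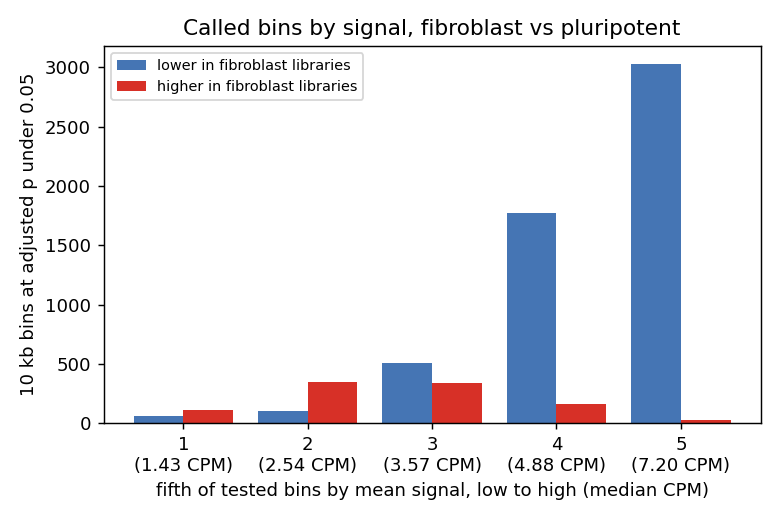
Number of 10 kb bins past an adjusted p of 0.05 (y axis) in each quintile of tested bins by mean signal, from low to high (x axis, with the median CPM of the quintile). Blue bars count bins lower and red bars bins higher in the fibroblast libraries; the highest quintile holds 3028 lower and 31 higher bins.

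The second comparison set the iPS libraries against the ES library. On the log2(CPM + 1) scale the largest difference was on chromosome 17, where bin 35640001 to 35650000 had 53.3 ± 4.85 CPM (SD, n = 2) in the iPS libraries and 2.80 CPM in R1, and its neighbour 35630001 to 35640000 had 29.0 ± 2.72 against 4.33 CPM. These 2 bins were also high in the fibroblast library titled TSKM (38.6 and 22.8 CPM) and low in the one titled OSKM (3.70 and 2.59 CPM). Without an input library, extra DNA copies and more 5hmC give the same rise in reads. On chromosome 11, bins 71070001 to 71080000 and 71030001 to 71040000 had 4.58 ± 0.212 and 4.42 ± 0.237 CPM in the iPS libraries. R1 had 1 and 3 reads in them, so that their CPM ratios, 86.8 and 27.9, were above that of bin 35640001 of chromosome 17. At 0.0528 and 0.158 CPM, R1 lay below the median of the lowest quintile of bins, 1.43 CPM. Whether fewer DNA copies, poor mapping or less 5hmC gave these low counts was not tested. Bin 68680001 to 68690000 of chromosome 13 had 5.51 ± 0.559 CPM in the iPS libraries and 0.370 in R1.

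Bins lower in the iPS libraries included 123830001 to 123840000 on chromosome 9, where R1 had 11.9 CPM and the iPS libraries were 11.4-fold lower, and 116610001 to 116620000 on chromosome 11, with 2.59 ± 0.428 CPM, 7.69-fold below R1. Bin 43740001 to 43750000 of chromosome 3 had 15.1 ± 5.13 against 68.1 CPM, and bin 96130001 to 96140000 of the same chromosome 4.42 ± 0.448 against 19.3. Bin 116840001 to 116850000 of chromosome 12 had 2.73 ± 0.384 against 12.8 CPM. In the chromosome 12 bin the fibroblast library titled OSKM, with a 129 strain label like R1, had 15.6 CPM and the one titled TSKM 3.21. The split was alike in the bins of chromosome 9 (6.87 against 1.19 CPM) and chromosome 11 (13.5 against 2.57). Bin 43740001 of chromosome 3 had 81.1 against 31.4 CPM. In bin 96130001 of chromosome 3 R1 stood above both fibroblast libraries, at 5.19 and 2.61 CPM. The longest stretch of higher bins was 130 kb on chromosome 11, from 70980001 to 71110000, with 0.357 CPM per bin in R1, 1.98 in the fibroblast library titled OSKM and 3.14 to 3.57 in the others. A 100 kb stretch on chromosome 4, from 111910001 to 112010000, had 0.0739 and 0.0480 CPM in R1 and the library titled OSKM and 1.16 to 1.64 in the others.

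In limma's test 16574 of 245981 bins passed, 7492 higher and 9082 lower in the iPS libraries (54.8% lower; 69.2% of 12610 in limma-voom with median-of-ratios scaling and 46.3% of 15583 with scaling by library size). The single ES library was assumed to vary like the other groups, and strain label and passage (20 to 25 for R1, 8 to 15 and 10 to 15 for the iPS lines) differed along with the group. Without TSKM-iPS 10946 bins passed. Chromosome 8 held 2089 of the lower bins and 77 of the higher ones, so that 17.6% of its bins were called. Over all chromosomes, calls of iPS against ES turned with signal as well, from 968 higher and 391 lower in the lowest quintile to 1548 higher and 3929 lower in the highest. Outside chromosome 8, 7415 bins were higher and 6993 lower. A fit without chromosomes 6 and 8 called 6550 higher and 7288 lower, and with libraries scaled per chromosome 59.0% of calls were lower.

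The read level of chromosome 8 was higher in R1 as a whole. The median ratio of R1 to the median of the other 4 libraries was 1.23 on chromosome 8. TSKM-iPS on chromosome 6 had 1.07, and all other libraries and autosomes ranged from 0.936 to 1.06. In 5 Mb windows of chromosome 8 the R1 ratio was between 1.13 and 1.41, and over 1.1 in all 27. On chromosome 6 the TSKM-iPS ratio was over 1.1 in 10 of 30 windows, up to 1.36. The median X signal was 33.4% of the autosomal one in R1, 34.5% and 35.1% in the fibroblast libraries and 30.6% in both iPS libraries.

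**Figure D3:**
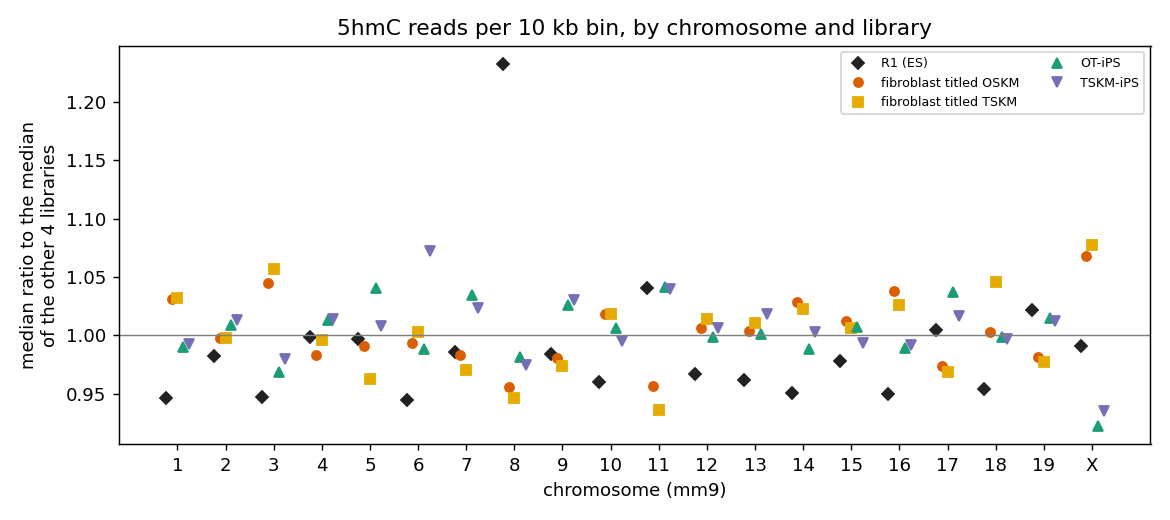
Median over 10 kb bins of each library's normalised reads divided by the median of the other 4 libraries (y axis, a ratio that does not start at 0), by chromosome (x axis). Each point is 1 library; R1 on chromosome 8 stands at 1.23.

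The third comparison set the iPS lines, made with different factors, against each other, with 1 library each and no test. By correlation they were the most alike of all pairs, with a Pearson value of 0.956 across bins, which are not independent replicates. By shared enriched windows the fibroblast pair was more alike (Jaccard index 0.547 against 0.518). The log2 ratio had an SD of 0.256 over 169890 bins, where counting error alone gives 0.218. TSKM-iPS was over 2-fold higher than OT-iPS in 67 bins and over 2-fold lower in 31. The highest ratio was 3.47 (95% exact interval 2.50 to 4.90, counting error only, as for all intervals here) in bin 137630001 to 137640000 of chromosome 5, with 172 reads against 47. Of the 8 highest, 4 lay on chromosome 6 between 114410001 and 129400000, at 2.44 to 2.63-fold, on the chromosome where part of the windows were raised in TSKM-iPS. TSKM-iPS was lowest relative to OT-iPS in bin 12190001 to 12200000 of chromosome 12, 2.54-fold lower (interval 1.71 to 3.83). Bins 57320001 to 57340000 and 57350001 to 57360000 of chromosome 17 were 2.32 to 2.47-fold lower. In bin 57350001 TSKM-iPS had 6.62 CPM, near the fibroblast libraries at 6.39 and 6.06, while OT-iPS and R1 had 16.0 and 15.9.

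The fibroblast libraries were compared in the same way. Their strain labels differ, 129 for the one titled OSKM and OG2-GFP for the one titled TSKM. Differences between these libraries can therefore follow strain as well as factors or days of doxycycline. Their correlation was 0.945, and the log2 ratio had an SD of 0.257 over 187347 bins, with 0.220 from counting error. The library titled TSKM was over 2-fold higher in 68 bins and over 2-fold lower in 130. The highest ratios were on chromosome 17, 10.4 (interval 8.26 to 13.4) in bin 35640001 and 8.79 (6.63 to 11.9) in bin 35630001. The lowest were on chromosomes 12 and 9. Bin 116830001 to 116840000 of chromosome 12 was 5.82-fold lower (interval 3.84 to 9.12), and bin 123830001 to 123840000 of chromosome 9 was 5.76-fold lower (3.77 to 9.11). Both of these bins were also low in the iPS libraries, which share the OG2-GFP label, and high in R1.

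**Figure D4:**
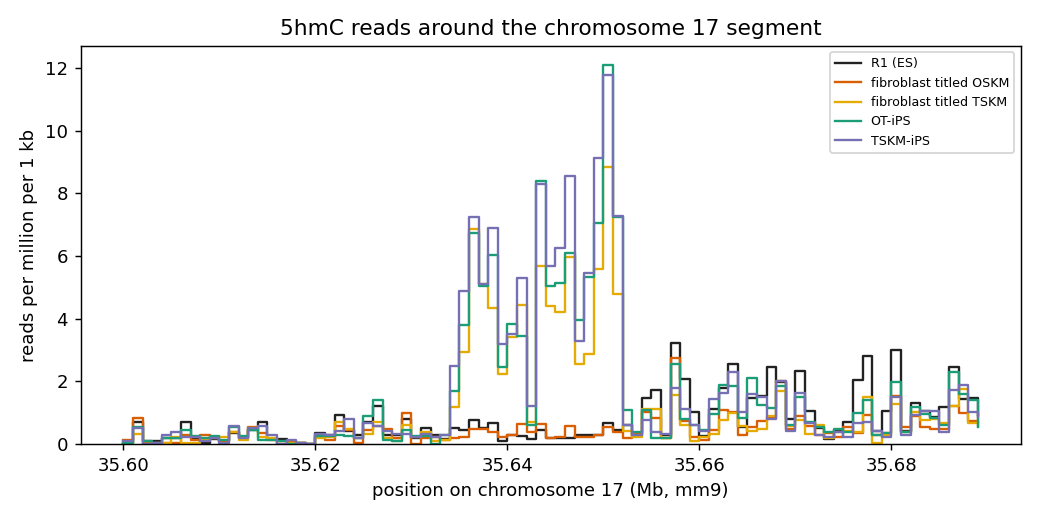
CPM in 1 kb windows (y axis) along chromosome 17 of mm9 (x axis, Mb), 1 line per library. From 35634001 to 35652000 OT-iPS, TSKM-iPS and the fibroblast library titled TSKM rise above R1 and the fibroblast library titled OSKM, with 94.0, 106 and 76.1 against 6.84 and 6.79 CPM (not TMM-scaled) in the whole segment.

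The libraries were last compared by the 1 kb windows enriched in each at equal depth. R1 had 158686 enriched windows, the fibroblast library titled OSKM 120649, the one titled TSKM 131456, OT-iPS 124652 and TSKM-iPS 100953. All 5 shared 46187. A further 6620 were enriched in the 3 pluripotent libraries alone and 7124 in both fibroblast libraries alone. Some sets that follow no class were as large, most of them with R1, which had the most enriched windows. There were 10973 in exactly R1 and both fibroblast libraries, 8852 in exactly R1 and the fibroblast library titled TSKM, 7454 in exactly R1 and OT-iPS and 6889 in both iPS libraries alone, while the other sets of 2 or 3 libraries held 892 to 6003. Joined into regions of 3 or more windows, the pluripotent set gave 146 regions and the fibroblast set 8. The region with the most windows, on chromosome 8 from 123091001 to 123106000, had 64.4, 40.2 and 34.2 reads per window in R1, OT-iPS and TSKM-iPS and 12.2 in each fibroblast library. Among the fibroblast regions, that on chromosome 17 from 5599001 to 5610000 had 33.5 and 35.5 reads per window, above all pluripotent libraries. The share of windows common to a pair was highest for the fibroblast pair (Jaccard index 0.547) and the iPS pair (0.518), and 0.355 to 0.460 for the rest. The 253474 windows enriched in at least 1 library held 34.8% ± 3.82 of reads (SD, n = 3) in the pluripotent and 34.4% ± 0.0887 (SD, n = 2) in the fibroblast libraries. The difference of 0.414 points was smaller than the spread between pluripotent libraries.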

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

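The test on chromosome M was chosen after its values were seen. Reads on chromosome M and chromosome Y were outside the comparisons, and all lay above the limit that a count of 0 allows. Chromosome M held 0.171% and 0.166% of reads in the fibroblast libraries titled OSKM and titled TSKM, and 0.0621%, 0.0646% and 0.0676% in R1, OT-iPS and TSKM-iPS. These are shares of all reads, not collapsed. The fibroblast mean was 2.61 times the pluripotent one (exact two-sided permutation p = 0.1, the smallest that 3 against 2 libraries allow), and 1.40 times with collapsed reads. Collapsing keeps at most 1 read per strand and position, and the last read on chromosome M ended at 16303. With 36938 and 37743 reads there in the fibroblast libraries, collapsing lowers the ratio even without PCR copies. The lower ratio therefore does not show how much of the difference came from PCR copies. Chromosome Y held 0.137% of reads in R1, 0.154% in the fibroblast library titled OSKM, 0.338% in the one titled TSKM, 0.142% in OT-iPS and 0.263% in TSKM-iPS. These values are given without an explanation.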

How the results depend on the processing

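Removal of the signal trend, strain label as a covariate, leaving out chromosomes 6 and 8, and uncollapsed reads for enriched windows were alternatives chosen after results were seen; the pseudocounts and the settings for iPS against ES had been listed for gene bodies and were applied to bins.

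For fibroblast against pluripotent 6461 bins were called from all 5 libraries. Without the fibroblast library titled OSKM 0 were called (0 higher and 0 lower), and without the one titled TSKM 1. These fits hold 1 fibroblast library, assumed to vary like the pluripotent ones, which alone give the spread. For bin 91550001 of chromosome 8 the log2 fold change was -1.52 with all libraries and -1.48 and -1.56 in these fits, and for bin 73270001 of chromosome 17 it was 0.94, 1.19 and 0.69. Without R1, which is the same as iPS alone against fibroblasts, 32416 were called (12550 higher and 19866 lower), and 37033 with 3 groups (12419 higher and 24614 lower). Without OT-iPS 1839 were called and without TSKM-iPS 4072. Scaling by library size gave 3343 lower bins, no filter 516 higher bins, and bins of 50 kb 3072 higher bins. With the signal trend removed 1736 were called (290 higher and 1446 lower), and with the strain label as a covariate 15835 (3629 higher and 12206 lower). That covariate also takes up the difference of R1 from the iPS libraries. Lower bins stayed the more frequent in every setting that called more than 1 bin.

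For iPS against ES, 16574 bins were called. Without TSKM-iPS 10946 were called (4410 higher), without the fibroblast library titled OSKM 16593 (7627 higher), and without a filter 9523 (4078 higher and 5445 lower). Limma-voom with median-of-ratios scaling gave 3881 higher bins. Lower bins were 54.8% of calls, but 46.3% with scaling by library size, a scaling that moved the median log2 fold change by 0.02. Outside chromosome 8, which held 2089 lower and 77 higher bins, 7415 were higher and 6993 lower. A fit without chromosomes 6 and 8 called 6550 higher and 7288 lower, and scaling per chromosome 5983 higher and 8626 lower.

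The 20 named bins kept their sign in all 330 values under alternatives. They were picked as the most extreme calls, and the groups compared did not overlap in any of them. A kept sign was thus favoured from the start and says little on robustness. The fits without R1 and of iPS alone against fibroblasts are the same, and both are counted. In 21 of these the adjusted p of limma rose above 0.05, 19 of them on leaving out a fibroblast library in the class test. Only bin 66410001 of chromosome 5 was still called without the fibroblast library titled TSKM. Bin 43740001 of chromosome 3 lost its call between iPS and ES without a filter and without the fibroblast library titled TSKM.

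Enriched windows at a Poisson p under 1e-03 were 248121 in R1, 201765 and 219651 in the fibroblast libraries titled OSKM and TSKM, 209234 in OT-iPS and 192434 in TSKM-iPS. Under 1e-08 they were 104457, 77414, 82385, 79357 and 57389 in the same order. The share of reads in windows enriched in any library, pluripotent minus fibroblast, reversed to -0.734 points with 500 bp windows and -0.119 with all reads. It rose to 1.73 with 2 kb windows and 0.705 at a p under 1e-03. For these and the other counts that moved, the cause was not tested.

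In bins of 50 kb correlations rose. With R1 they were 0.944 for the fibroblast library titled OSKM, 0.936 for the one titled TSKM, 0.963 for OT-iPS and 0.960 for TSKM-iPS. The fibroblast pair had 0.980 and the iPS pair 0.986. The fibroblast library titled OSKM had 0.956 with OT-iPS and 0.953 with TSKM-iPS, and the one titled TSKM 0.952 and 0.951. With all reads, 52 bins were over 2-fold lower in TSKM-iPS than in OT-iPS, and 112 over 2-fold higher in the fibroblast library titled TSKM than in the one titled OSKM.

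No paired analysis was possible because the libraries that share a replicate number are different lines with nothing in the labels that pairs them. Gene body, promoter, gene list and reprogramming factor results and the correction for GC content were planned and not run, since no mm9 annotation or sequence was used here.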

Other observations

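Tests on the high-signal bins, the strain labels, the chromosome 17 segment and chromosome 8 against other autosomes were chosen after results were seen; those on windows and low-signal bins of chromosome 8, and on the share of reads in enriched windows, were written down before they were run.

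Libraries that share a strain label differed together at a small number of places. The 3 libraries with the OG2-GFP label (OT-iPS, TSKM-iPS and the fibroblast library titled TSKM) and the 2 with a 129 label were found to part in a scan of 250 bp windows, in which all 10 ways to divide the libraries into 3 and 2 were counted. At over 3-fold, 77 windows followed the strain labels, of which 52 were higher with the OG2-GFP label and 25 with the 129 label. Another 52 followed the fibroblast and pluripotent classes, and the highest total of the other 8 divisions was 6. Of the windows higher with the OG2-GFP label, 36 lay on chromosome 17 between 35635501 and 35651750, so that the 77 are not as many separate places. Another 3 lay on chromosome 4 between 108553751 and 108554500, with 115 to 125 reads against 1 and 2. Of those higher with the 129 label, 3 lay on chromosome 11 between 116612251 and 116626750 and 3 on chromosome 9 between 123832501 and 123844500.

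The first pattern was the raised read level of chromosome 8 in R1. The hypothesis that part of the R1 cells carried extra copies of it goes with a ratio over 1.1 in 100% of its 5 Mb windows. A gain of 5hmC at enriched bins alone is argued against, since the ratio was 1.12 in the quintile of bins with the lowest signal. Set against the same quintiles of the other autosomes, chromosome 8 was 1.25 times higher in the lowest and 1.24 times in the highest. No karyotype or input library was used here, so copy number stays a hypothesis.

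The second pattern was the fall of high-signal bins in the fibroblast libraries. A smooth loss with signal level is argued against as the whole cause, since 26.0% of the lower calls (1421 of 5467) were still lower calls after each library's trend on signal was removed. Over all lower calls the median log2 fold change went from -0.68 (SD 0.12) to -0.57 (SD 0.14), so that such a loss may be part of the cause. More unspecific background remains open: windows enriched in the fibroblast libraries alone were 35.3 times as many as in a simulated dilution of the pluripotent profile, but that simulation assumes a flat background and excludes nothing. GC content was not tested, and a true difference between cell types remains open and untested.

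An expectation written down before enriched windows were counted was not met, namely that a smaller share of fibroblast reads would lie in them. At equal depth the shares in windows enriched in any library differed by 0.414 points, and both fibroblast shares lay inside the pluripotent range. In the data 7124 windows were enriched in both fibroblast libraries alone. The dilution planned for this expectation gave a simulated mean of 978.5, so the ratio of observed to simulated was 7.28. That is above the limit of 2 written down to exclude background, yet both explanations were left undecided because there was no difference to explain. The dilution matched to high-signal bins was added only after this value was seen.

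The third pattern was the set of bins that differed between iPS and ES libraries. Copy number of chromosome 8 is argued against as the main source, since 81.0% of the called bins lay outside chromosomes 6 and 8. A strain difference was looked for in the fibroblast pair, with 1 library of each label. Over all called bins the sign matched in 48.8%. The same pair entered the spread of the test, so bins in which it differs were less readily called. The share also cannot decide on strain, since a difference found in R1 but not in the other 129-labelled library leaves no mark in that pair. In bin 71070001 of chromosome 11, R1 had 0.0528 CPM and the fibroblast library titled OSKM 3.31. Over the 451 called bins with a log2 difference over 1 the sign matched in 72.3%. For those, sequence or copy differences between strains may contribute; in the 18 kb segment of chromosome 17, 13.5 times higher with the OG2-GFP label, whether extra DNA copies, such as those of a reporter transgene, or more 5hmC raised the reads was not tested. Passage, and reprogramming itself, remain open and untested.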
